A study of Mus musculus with 48 samples.

How the data were processed

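Polyadenylated RNA from brainstem, cerebellum, cortex and hippocampus of 12 mice was sequenced, giving 48 libraries. Per the labels' protocols, tissue was frozen, RNA was isolated with the RNeasy kit and treated with DNase, and libraries were made with the KAPA mRNA HyperPrep kit, which selects polyA RNA with oligo-dT beads, fragments it, ligates barcoded adapters and amplifies by PCR. The labels do not say whether strand was kept or used in counting, so a gene and an overlapping antisense gene cannot be told apart here. The mice carried a D801N or an E815K allele of Atp1a3 on 1 chromosome, or no mutant allele (WT), on a B6C3 background. Each genotype had 4 mice, 2 female and 2 male, and every mouse gave all 4 regions. The mouse was the replicate, and mice are named by genotype and number, as in the sample titles (WT_430).

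The deposited gene table holds estimated counts per gene, rounded to whole numbers, for 57132 genes in 48 columns. The deposited transcript table holds estimated counts for 149138 transcripts in the same libraries. Per the submitters' processing notes, cutadapt 4.4, kallisto 0.48.0 and DESeq2 1.38.3 were used with the GRCm39 genome build. The role of each tool, its settings and the annotation release are not given in the sources used here. kallisto assigns reads to transcripts by compatible sequence and divides reads that match several transcripts by an estimate, so counts of near-identical copies, such as pseudogenes and gene families, are uncertain. The number of per-sample columns left unused was 0. Estimated counts were rounded before every count test. The reference at hand was GRCm38, another build than that of the tables, so no coordinates are printed. GRCm38 gene positions (GENCODE annotation) served only to find which genes neighbour Atp1a3, with 20045 to 20532 of the tested identifiers of a region matched without their version.

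Total counts per library ran from 26899337 to 39069531. Intervals given for ratios of small counts are exact 95% intervals, and they cover counting error only, since PCR copies were not marked by molecular identifiers. Each region was fitted on its own with all 12 libraries, so that the 3 genotypes shared an estimate of the spread, with sex as a covariate. Genes were kept by edgeR's filterByExpr (minimum count 10, minimum total 15), libraries were scaled by the trimmed mean of M values (TMM), and genotypes were compared with edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3). P-values were adjusted by Benjamini-Hochberg over the genes tested in a comparison, and a gene was called at an adjusted p under 0.05. CPM values (counts scaled to a common library size), computed from the deposited counts, use the TMM-scaled library size and are given as mean ± SD over 4 mice, except for the region markers, which use the plain total. Log2 fold changes are given with their standard error (SE), obtained from the fold change and its F statistic.

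Effects averaged over regions were tested with limma 3.58.1 (empirical Bayes with trend) on the mean over 4 regions of each mouse's log2 CPM, with a prior count of 2. The same values served to test whether an effect differed between sexes. Whether an effect differed among regions was tested in edgeR with the 3 region by genotype terms together. For the gene lists, limma's camera with a preset correlation of 0.01 was run on voom values for 42 lists in the 8 comparisons of a mutant with WT, and Benjamini-Hochberg adjustment covered all 330 tests. Camera with a correlation estimated per list and limma's fry, a rotation test of whether a list's genes move on balance one way, were run beside it. Members of a list were also adjusted over the list alone. The lists held Na,K-ATPase subunits, channels, receptors, neuron and glia types, stress and immune responses, mitochondrial genes, clock genes and markers of tissue that a dissection can carry over. Shares of Atp1a3 transcripts were compared by two-sided exact permutation tests, and calls near Atp1a3 by two-sided Fisher's exact tests.

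The groups, tests, lists and most alternatives were fixed before the data were examined. So was the rule for named genes. It takes Atp1a3, then up to 8 rising and 8 falling called genes with the largest change, a mean of at least 1 CPM, a symbol that is not a clone or pseudogene name and no overlap between the 4 mutant and the 4 WT libraries, then up to 12 called list members by p. For E815K against D801N it takes up to 5 each way, and where fewer than 5 genes qualify it takes the 3 with the smallest p. For dependence on region or sex it takes up to 5 genes, and for calls shared by both mutants or by several regions up to 10. Called members of a list are also named where the list is described. Other genes outside the rule are named as such. Some genes that the rule takes are not reported here.

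The alternatives were DESeq2's Wald test (DESeq2 1.42.0), limma voom, DESeq2's size factors, no filter on low counts, a stricter filter (1 CPM in 4 libraries), no sex covariate, fitting only the groups compared, each mouse left out in turn, and a term for the range of mouse numbers. Numbers run from 430 to 442 and from 550 to 561. All D801N mice are in the low range, all E815K mice in the high range, and WT mice in both, so the range may stand for a cohort, which no label states. For averages, a prior count of 0.5, summed counts and a fit of all libraries with a correlation within mice were added. For region dependence, the mouse as a block and DESeq2's likelihood ratio test were added. Chosen after seeing the data were a robust quasi-likelihood fit, leaving out libraries that stand apart (D801N_442 in every region, WT_430 and E815K_558 in brainstem), the range term for gene lists, and separate pairs of WT mice for the genes called higher in both mutants.

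The same mice gave all regions, which pairs the libraries across regions. Deviations from the group means over 10962 genes correlated between regions of a mouse in all 72 cases (r from 0.488 to 0.844, median 0.714; genes are not independent replicates). Between different mice of a group the median r was -0.214. Given the positive r within mice, its sign is set by construction, since deviations from a group mean cancel out over its mice. No pair of libraries within a group matched within sampling noise: the squared difference of counts over its sampling variance averaged at least 14.2 over genes in each of the 72 pairs.

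Scripts were tested on simulated counts drawn from the real means and library sizes with 200 changed genes, before the real data were run. For D801N against WT in cerebellum (20916 genes), 55.2% of genes changed 1.5-fold, 83.6% of those changed 2-fold and 97% of those changed 4-fold were called, with 11 unchanged genes called. For the same comparison in brainstem (20603 genes) the shares were 56.7%, 80.6% and 100%, in cortex (21197 genes) 56.7%, 82.1% and 100%, and in hippocampus (20699 genes) 46.3%, 82.1% and 97%. For the average over regions (18619 genes) they were 86.6%, 97% and 100%, for the sex term (18588 genes) 47.8%, 80.6% and 98.5%, and for the region terms (23759 genes) 41.8%, 73.1% and 97%. Each simulated library was drawn independently, without a shared effect of the mouse. Real regions of a mouse deviated together, so the shares for the average and the sex term are likely too high. Camera called 2 of 2 changed lists and 0 of the other 40 in independent simulated genes, with the preset and with an estimated correlation, which says nothing about lists whose genes vary together. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.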

Results

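Gene expression was compared in the brains of mice that carry 1 of 2 mutant alleles of Atp1a3, which encodes the α3 subunit of the Na,K-ATPase, the pump that restores sodium and potassium gradients in neurons. Both alleles are associated with alternating hemiplegia of childhood (AHC), a neurological disorder with episodes of paralysis. Brainstem, cerebellum, cortex and hippocampus were taken from 4 heterozygous D801N mice, 4 heterozygous E815K mice and 4 WT mice, with 2 females and 2 males in each group, which gave 48 libraries. Total counts per library were 27538895 to 36384623 in brainstem, 28424393 to 33806930 in cerebellum, 26899337 to 37077114 in cortex and 31714362 to 39069531 in hippocampus. Mice are named by genotype and number, as in the sample titles.

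The labels for region and sex were checked with genes chosen for this. Slc6a5, the glycine transporter of inhibitory hindbrain neurons, was at 136 to 731 CPM in brainstem libraries and at most 63.8 CPM elsewhere. Gabra6, a GABA receptor subunit of cerebellar granule cells, was at 299 to 721 CPM in cerebellum and at most 10.1 CPM elsewhere. Satb2, a transcription factor of cortical projection neurons, was at 52.9 to 81.1 CPM in cortex and at most 25.5 CPM elsewhere, and Prox1, a transcription factor of dentate granule cells, was at 102 to 156 CPM in hippocampus and at most 95 CPM elsewhere. Xist, transcribed from the inactive X chromosome, had 10362 to 38604 counts in libraries labelled female and 1 to 59 in those labelled male. The Y-linked gene Ddx3y had 1 to 14 and 1500 to 4047 counts in the same libraries. Every library lay on the side of its labels in these genes. WT_430 gave the lowest brainstem level of Slc6a5, with 4659 counts against 12253 to 24246 in the other brainstem libraries. These markers therefore do not show that its dissection matched the others.

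The first question was whether the mutant alleles changed the level of Atp1a3 itself (ENSMUSG00000040907.16). In brainstem it was at 3230 ± 173 CPM in WT, 3150 ± 410 CPM in D801N and 3120 ± 115 CPM in E815K (mean ± SD, n = 4 mice each, here and throughout). In cerebellum the levels were 1940 ± 46.2, 1780 ± 147 and 2110 ± 170 CPM, in cortex 1590 ± 64.6, 1740 ± 72.1 and 1730 ± 131 CPM, and in hippocampus 2550 ± 95, 2590 ± 262 and 2850 ± 210 CPM, in the same order. Log2 fold changes against WT ran from -0.13 to 0.16, and none of the 8 passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, where the lowest adjusted p was 0.387 (D801N cerebellum). Averaged over regions, the log2 fold change was -0.01 ± 0.056 (SE) in D801N and 0.09 ± 0.056 (SE) in E815K, with limma adjusted p = 0.968 and 1. The shares of 5 Atp1a3 transcripts were compared in 40 two-sided exact permutation tests, of which 0 had p under 0.05. The lowest exact p was 0.0857, and the lowest adjusted p was 0.828. With 4 against 4 mice the exact p has a floor too high for a single transcript to pass adjustment over 40 tests. These tests therefore do not show that the shares are unchanged. The counts do not separate the mutant from the WT allele.

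Calls at an adjusted p under 0.05 were concentrated in cerebellum and brainstem. In cerebellum, 621 of 20938 genes were called between D801N and WT (388 higher, 233 lower), 26 between E815K and WT (26 higher, 0 lower) and 240 between E815K and D801N (90 higher in E815K, 150 lower). In brainstem, 0 of 20664 genes were called between D801N and WT, 106 between E815K and WT (103 higher, 3 lower) and 150 between E815K and D801N (136 higher in E815K, 14 lower). In cortex (21197 genes) and hippocampus (20761 genes) each of the 3 comparisons gave 0 calls.

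**Figure D1:**
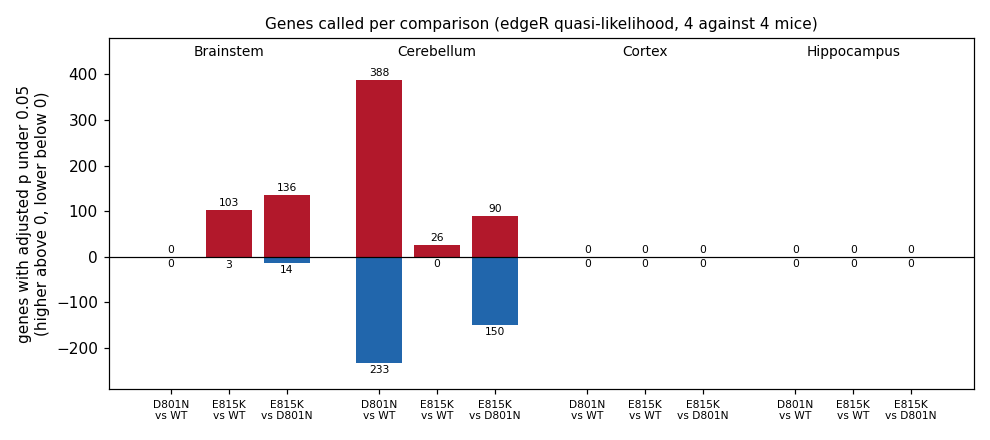
Genes called per comparison by edgeR's quasi-likelihood test at an adjusted p under 0.05 (y axis, number of genes; genes higher in the first group above 0, genes lower in it below 0), for each pair of genotypes in each region (x axis), with 4 mice per group. The tallest bars are those of D801N against WT in cerebellum, with 388 genes higher and 233 lower, and all bars for cortex and hippocampus are at 0.

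E815K mice were compared with WT in brainstem to find which genes this allele changed there. Of the 106 called genes, 13 were members of the list of activated microglia, 6 of homeostatic microglia and 8 of reactive astrocytes. Itgax (ENSMUSG00000030789.10), the integrin CD11c of activated microglia, was at 8.88 ± 4.84 CPM in E815K and 0.411 ± 0.0770 CPM in WT (log2 fold change 4.42 ± 0.52 SE). C4b, a complement component, rose from 42.9 ± 13.5 to 183 ± 38.3 CPM (2.08 ± 0.24), and Csf1r (ENSMUSG00000024621.17), the receptor that microglia need to survive, rose from 49.8 ± 3.51 to 89.1 ± 10.5 CPM (0.84 ± 0.11). The adjusted p of all 3 was 0.0102 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Cst7, which encodes the protease inhibitor cystatin F, had 370 counts in the E815K libraries and 2 in the WT libraries, a ratio of CPM of 190 with a counting interval of 52.2 to 1570.

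Of 20 tested genes of activated microglia, 13 rose and 0 fell in E815K brainstem, and 19 rose when adjusted over the list alone. They included the receptor Clec7a (log2 fold change 4.09), the lysosomal genes Cd68 (1.75) and Ctsd (1.0), and Trem2 (1.47) and Tyrobp (1.97), a receptor and its signalling adaptor. Of 17 genes of homeostatic microglia, 6 rose and 0 fell (9 adjusted over the list alone), namely Hexb (0.90), Csf1r, the complement genes C1qa (1.52), C1qb (1.55) and C1qc (1.52), and the protease Ctss (1.34). Of 21 genes of reactive astrocytes, 8 rose and 0 fell (14 adjusted over the list alone), among them the filament genes Gfap (1.70) and Vim (1.13) and the protease inhibitor Timp1 (2.58). Camera's adjusted p was 4.49e-34, 2.16e-15 and 1.20e-20 for the 3 lists. None of these held when the correlation was estimated, with adjusted p = 0.174, 0.245 and 0.167 with an estimated correlation, while limma's fry gave adjusted p = 0.0193, 0.0825 and 0.0134. Genes of MHC class I, which present peptides to T cells, and interferon-induced genes had medians of 0.60 and 0.45 on the log2 scale with 0 of 13 and 0 of 24 called by edgeR (6 and 0 adjusted over the list alone; camera adjusted p = 1.76e-07 and 7.55e-07). Those adjusted p were 0.324 and 0.479 with an estimated correlation. Other called genes with large changes were Lgals3 (2.89), which encodes galectin-3, Ly9 (2.83) and Cd52 (2.30), surface proteins of immune cells, and Lyz2 (2.30) and Mpeg1 (2.21), which encode antibacterial proteins of macrophages. The genes that fell by the rule were Scrt1, a transcription factor of neurons (-0.41 ± 0.077, from 193 ± 17.1 to 146 ± 9.13 CPM), and Hapln4, a link protein of perineuronal nets (-0.38 ± 0.061, from 189 ± 7.43 to 145 ± 4.43 CPM), with edgeR's adjusted p = 0.0431 and 0.0184. Of 16 subunits and partners of the Na,K-ATPase, 1 rose, Fxyd1 (0.66), and 1 of 17 astrocyte genes rose, Mlc1.

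Choroid plexus genes had a median log2 fold change of 2.38 in this comparison with 0 of 16 called, and their marker Ttr was at 2970 CPM in E815K_558 against 3.47 to 229 CPM in the other 11 brainstem libraries. WT_430 differed in hindbrain genes, with Hoxb5 at 0.706 CPM against 30.7 to 82.1 CPM in the others. Without the libraries of WT_430, E815K_558 and D801N_442, 75 genes were called, of which 56 were among the 106. The number of calls depended on single mice. It was 0 without WT_550 or E815K_557 (smallest edgeR adjusted p 0.0521 and 0.0525), 1 without WT_430, 35 without WT_561, 39 without E815K_555 and 47 without WT_434. All 106 genes kept their direction and an unadjusted p under 0.05 in each of the 8 fits. These genes were picked in the full fit, which shares most libraries with each of the 8, so this was likely in advance. With a term for the range of mouse numbers, which compares 4 mutant with 2 WT mice, 0 of the 106 genes were called, and all kept their direction (median log2 fold change 1.14 before and 1.12 after, median SE 0.18 and 0.23). Genes picked with all 4 WT mice tend to have a narrow spread among them, so a steady fold change was likely in advance.

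D801N mice showed no called gene in brainstem. The 3 genes with the smallest p were Cd83, a surface protein of activated immune cells (53.9 ± 1.80 CPM in D801N and 41.8 ± 1.61 in WT, log2 fold change 0.37 ± 0.060), Apbb2, a binding partner of the amyloid precursor protein (0.34 ± 0.058), and Glipr2 (0.92 ± 0.16), each with edgeR's adjusted p = 0.449. Genes of activated microglia had a median log2 fold change of 0.11, with 0 of 20 called. Neuropeptides and secreted factors regulated by neuronal activity had a median of 0.34 with 0 of 18 called (6 adjusted over the list alone; camera adjusted p = 7.80e-08, and adjusted p = 0.245 with an estimated correlation). Hox genes of the hindbrain had a median of 1.01 (camera adjusted p = 1.96e-08, and adjusted p = 0.479 with an estimated correlation), in a comparison that includes WT_430 with its low Hoxb5. edgeR called 0 genes, with 1775 at an unadjusted p under 0.05, DESeq2's Wald test called 55, and limma voom called 0. Without a filter on low counts edgeR called 386.

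Between E815K and D801N brainstems 150 genes were called, of which 81 were also called in E815K against WT, all in the same direction, in 2 comparisons that share the E815K libraries. Of the 150, 12 were members of the list of activated microglia, 6 of homeostatic microglia and 4 of reactive astrocytes. Itgax was at 8.88 ± 4.84 CPM in E815K and 0.454 ± 0.258 in D801N (log2 fold change 4.29 ± 0.52, edgeR's adjusted p = 0.0116), and Clec7a (4.61), Ly9 (3.45) and Cd52 (3.02) were also higher in E815K. Cst7 had 370 counts in E815K and 9 in D801N, a ratio of 42.6 (counting interval 22.2 to 93.9). Lower in E815K were Npas2, a transcription factor of the circadian clock (5.24 ± 0.503 against 9.81 ± 1.49 CPM, -0.90 ± 0.17, edgeR's adjusted p = 0.0394), Id2, an inhibitor of transcription factors (-0.90), Gabra5, a GABA receptor subunit (-0.53), the growth factor Tgfb3 (-0.50) and the heparan sulfate enzyme Hs3st5 (-0.48). All D801N mice have low numbers and all E815K mice high numbers, and with a term for the range 0 of the 150 genes were called. All of them, picked in the fit without the term, kept their direction, and 135 kept an unadjusted p under 0.05 (median log2 fold change 1.07 before and 0.94 after, median SE 0.18 and 0.31). Clec7a was then at 5.99, Itgax at 4.12, Ly9 at 4.18 and Cd52 at 2.48, while Cst7 went from 5.35 to 2.17, Npas2 to -0.37 and Id2 to -0.43. The count was 0 without D801N_440 or E815K_557, 34 without E815K_555, 42 without D801N_436, 62 without D801N_439, 84 without D801N_442 and 95 without E815K_558, and it was 11 when the WT libraries were left out of the fit.

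D801N mice differed most from WT in cerebellum. Th (ENSMUSG00000000214.12), which encodes tyrosine hydroxylase, the rate-limiting enzyme of catecholamine synthesis, was at 209 ± 53.7 CPM in D801N and 1.66 ± 0.373 CPM in WT (log2 fold change 7.01 ± 0.49). Scg2 (ENSMUSG00000050711.8), the precursor of secretoneurin in secretory granules, rose from 111 ± 8.03 to 352 ± 49.9 CPM (1.67 ± 0.11), and Atp1b1 (ENSMUSG00000026576.13), the β1 subunit of the Na,K-ATPase, rose from 1150 ± 69.9 to 1600 ± 68.9 CPM (0.48 ± 0.062). Grid2 (ENSMUSG00000071424.11), the glutamate receptor at parallel fibre synapses of Purkinje cells, fell from 301 ± 43.6 to 175 ± 10.6 CPM (-0.78 ± 0.092), and the growth factor Fgf7 fell from 18.6 ± 4.62 to 4.21 ± 1.23 CPM (-2.13 ± 0.22). The adjusted p of these genes in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment were 2.9e-05, 1.91e-05, 0.00215, 0.001 and 0.000546.

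**Figure D2:**
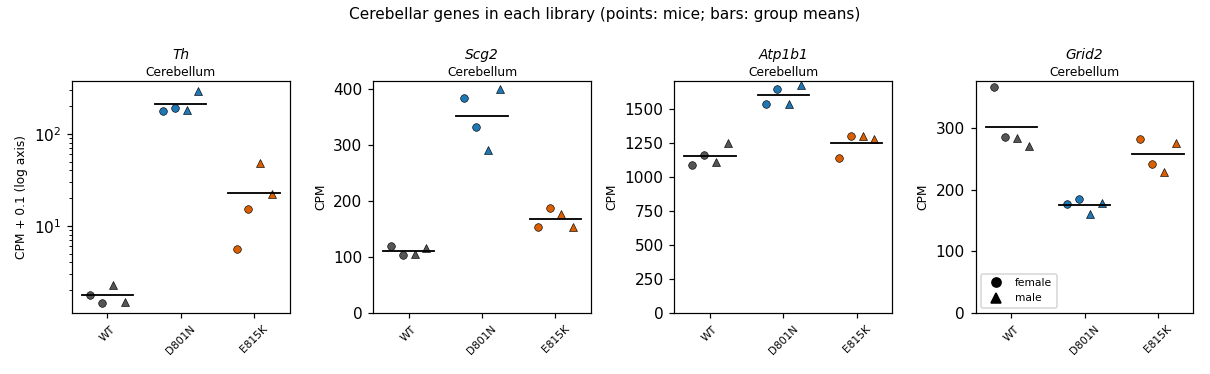
Th, Scg2, Atp1b1 and Grid2 in each cerebellar library (y axis, CPM, and CPM + 0.1 on a log axis for Th; x axis, genotype). Points are mice (circles female, triangles male) and bars are group means of 4 mice. Th lies at 176 to 289 CPM in D801N, 5.47 to 47.7 in E815K and 1.37 to 2.17 in WT.

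Further genes that rose in D801N cerebellum by the rule were the peptide precursor Tac1 (4.23 ± 0.81), the imprinted retrotransposon-derived gene Rtl1 (4.87 ± 0.39), Agmat (3.90), Fndc1 (3.15), the Ras-like GTPase gene Rasd1 (3.03) and the protease inhibitor Serpina3n (2.58). Trbc2, a constant segment of the T cell receptor β chain, had 751 counts in D801N and 3 in WT, a ratio of 238 (counting interval 81.1 to 1160). Genes that fell included Myo15a (-2.25) and Otof (-1.31), known for their part in hearing, Syt6 (-1.72), a synaptotagmin, Car9 (-1.69), a carbonic anhydrase, Bean1 (-1.40), the potassium channel gene Kcnh3 (-1.35) and the calcium-binding protein gene Cabp2 (-1.30). The edgeR adjusted p of these genes ran from 2.16e-05 (Fndc1) to 0.0345 (Kcnh3).

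Of 14 activity-regulated neuropeptides and secreted factors, 5 rose and 0 fell in D801N cerebellum (10 rose and 1 fell adjusted over the list alone), namely Scg2, Tac1, Vgf (1.58), Nptx2 (2.57), a pentraxin of synapses, and Adcyap1 (1.97 ± 0.22, from 5.81 ± 1.28 to 22.8 ± 3.63 CPM), which encodes the peptide PACAP. Camera's adjusted p was 7.79e-07, and adjusted p = 0.174 with an estimated correlation. Of 13 genes encoded in mitochondrial DNA 8 rose (8 adjusted over the list alone, median 0.29), with camera adjusted p = 1.78e-09 and adjusted p = 0.174 with an estimated correlation. Myelin and oligodendrocyte genes rose in 5 of 18 cases (9 adjusted over the list alone), among them Plp1 (0.47) and Mbp (0.58), and 4 of 12 genes of their precursors rose, among them Olig1 (0.53), with camera adjusted p = 5.76e-07 and 0.00311. For these 2 lists adjusted p = 0.426 and 0.45 with an estimated correlation. Of 15 subunits and partners of the Na,K-ATPase 2 rose, Atp1b1 and Nkain2 (0.51), and 0 fell (3 rose adjusted over the list alone).

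Ion channel genes fell in part in D801N cerebellum. Of 12 sodium channel genes 3 fell and 0 rose, Scn1a (-0.29), Scn2a and Scn8a (-0.26), and 6 fell and 1 rose adjusted over the list alone (camera adjusted p = 0.000515, and adjusted p = 0.245 with an estimated correlation). Of 18 calcium channel genes 2 fell, Cacnb4 and the T-type channel gene Cacna1g (-0.56, from 370 ± 31.1 to 250 ± 22.3 CPM), with 4 adjusted over the list alone (camera adjusted p = 0.00558, and adjusted p = 0.245 with an estimated correlation). Of 34 potassium channel genes 3 fell, Kcnab1 (-0.58), Kcnc1 and Kcnc3, and adjusted over the list alone 4 rose and 6 fell (camera adjusted p = 0.54). Granule cell genes fell in 3 of 15 cases, Gabra6 (-0.60), Cbln3 (-0.33) and Etv1 (-0.59), with 4 adjusted over the list alone (camera adjusted p = 0.000468, and adjusted p = 0.324 with an estimated correlation). Purkinje cell genes went both ways. Of 16, the glutamate transporter gene Slc1a6 (0.40) and Aldoc (0.42) rose, and Grid2, the cation channel gene Trpc3 (-0.52), the phospholipase gene Plcb4 (-0.37) and Arhgef33 fell, also when adjusted over the list alone (2 rose and 4 fell; camera adjusted p = 0.384).

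Glial genes rose in D801N cerebellum too. Of 19 genes of activated microglia 10 rose (15 adjusted over the list alone), including Apoe (0.44), Spp1 (1.22) and Itgax, which had 182 counts in D801N and 9 in WT (ratio 19.2, counting interval 9.9 to 42.7). Of 17 homeostatic microglial genes 6 rose (7 adjusted over the list alone), among them C1qa (1.22), and of 20 reactive astrocyte genes 5 rose (12 adjusted over the list alone), among them Gfap (1.39). Camera's adjusted p was 3.11e-13, 1.73e-06 and 8.68e-07, and adjusted p = 0.245, 0.341 and 0.245 with an estimated correlation. Glucocorticoid-induced genes had a median of 1.0 with 1 of 15 called, Cdkn1a (10 adjusted over the list alone; camera adjusted p = 6.00e-05, and adjusted p = 0.55 with an estimated correlation). In D801N_442 their member Fkbp5 was at 125 CPM, against 7.24 to 26.6 CPM in the other 11 cerebellar libraries. Choroid plexus genes had a median of 0.84 with 0 of 16 called, and meningeal genes 0.47 with 1 of 15 called, Col1a2.

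The count of 621 was 742 without D801N_442, of which 510 genes were shared. It was 397 without D801N_440, 367 without D801N_439, 358 without WT_561, 338 without WT_430, 268 without WT_550 and 249 without WT_434, and 241 when the E815K libraries were left out of the fit (230 shared). With the range term 152 genes were called (140 shared), and all 621 kept their direction with an unadjusted p under 0.05. These genes were picked in the fit without the term, which made little change likely. Their median log2 fold change was 0.59 without and 0.58 with the term, with a median SE of 0.11 and 0.14. Th, Scg2, Atp1b1, Grid2 and Fgf7 were still called then, with log2 fold changes of 6.80, 1.65, 0.54, -0.88 and -1.90, as were Itgax and C1qa. Calls lost with the range term included those of Tac1, Serpina3n, Myo15a, Kcnh3, Cabp2, Ccl3, Clec7a, C4b, Tyrobp, Mpeg1, Gfap, Lyz2 and Hvcn1, with edgeR's adjusted p from 0.0502 (Serpina3n) to 0.268 (Hvcn1). Calls lost when 1 mouse was left out were those of Tac1 (without WT_550, WT_434 or WT_561, edgeR adjusted p 0.0619 to 0.0669), Myo15a (without WT_550, 0.0548), Cabp2 (without WT_430, WT_434 or WT_561 or D801N_439 or D801N_440, 0.0513 to 0.088) and Kcnh3 (without WT_430, WT_550 or WT_561 or D801N_439, D801N_436 or D801N_442, 0.0543 to 0.106).

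E815K cerebellum showed 26 called genes, all higher than in WT. Itgax was at 3.75 ± 1.10 CPM in E815K and 0.0758 ± 0.0741 CPM in WT (471 and 9 counts, ratio 50.5, counting interval 26.4 to 111, edgeR's adjusted p = 0.000767). Gfap, the intermediate filament protein of astrocytes, rose from 90.5 ± 15.8 to 315 ± 98.1 CPM (log2 fold change 1.78 ± 0.22, adjusted p = 0.00906), C4b rose from 9.62 ± 2.87 to 45.7 ± 20.8 CPM (2.23 ± 0.32, 0.0225), and Csf1r rose from 18.3 ± 0.322 to 32.5 ± 3.73 CPM (0.83 ± 0.090, 0.00646), all by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Th was at 22.7 ± 18.1 CPM in E815K, with single mice from 5.47 to 47.7 CPM, and at 1.66 ± 0.373 CPM in WT (3.63 ± 0.47, 0.0104).

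Of 19 genes of activated microglia 5 rose (18 adjusted over the list alone), Itgax, Clec7a (3.55), Tyrobp (2.17), Lyz2 (1.57) and Ccl3, a chemokine with 82 counts in E815K and 1 in WT (ratio 79.1, counting interval 13.8 to 3160). Of 17 homeostatic microglial genes 6 rose (12 adjusted over the list alone), Csf1r, Ctss (1.27), Hexb (0.79), C1qa (1.37), C1qb (1.5) and C1qc (1.48). Of 20 reactive astrocyte genes 3 rose (11 adjusted over the list alone), Gfap, C4b and Serpina3n (3.02), and the complement gene C3 (2.93) was also higher. Camera's adjusted p was 4.52e-37, 1.80e-24 and 3.11e-13 for the 3 lists, and adjusted p = 0.142, 0.167 and 0.167 with an estimated correlation. Granule cell genes had a median of -0.24 with 0 of 15 called (8 fell adjusted over the list alone; camera adjusted p = 2.20e-10, and adjusted p = 0.167 with an estimated correlation). Choroid plexus genes had a median of 0.13 here.

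The number of calls was 4 without WT_550, 6 without WT_430, 11 without WT_561 or E815K_557, 12 without E815K_556 and 13 without WT_434, and 59 without the libraries of D801N_442. The calls of Itgax, Ctss and Csf1r held in all 8 fits without 1 mouse, those of Gfap and Serpina3n were lost without WT_550 (edgeR adjusted p 0.0566 for both), and that of Th without any of the 4 WT mice (0.0519 to 0.08). limma voom called 11 genes. With the range term 2 genes were called, Itgax among them (6.12, edgeR adjusted p 0.0347). All 26, picked in the fit without the term, kept their direction (median log2 fold change 1.70 before and 1.74 after).

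**Figure D3:**
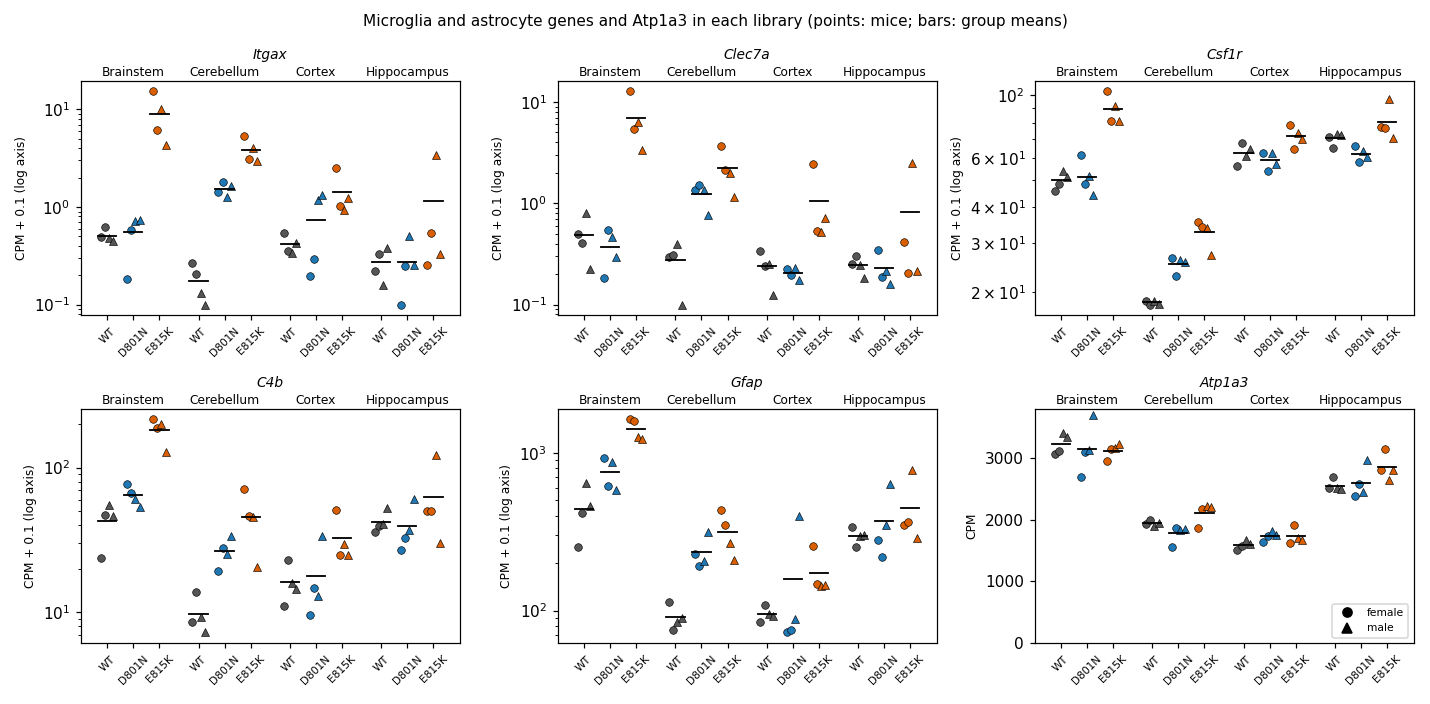
Itgax, Clec7a, Csf1r, C4b and Gfap (CPM + 0.1 on log axes) and Atp1a3 (CPM) in each library, by region and genotype (x axis). Points are mice (circles female, triangles male) and bars are group means of 4 mice. In brainstem the 4 E815K libraries lie above all WT libraries for the first 5 genes, as do both mutants in cerebellum. In cortex the 4 E815K libraries lie above all WT libraries for Itgax, Clec7a, C4b and Gfap, in hippocampus E815K_557 lies highest for the first 5 genes, and the groups of Atp1a3 differ little.

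Between E815K and D801N cerebella 240 genes were called, of which 180 were also called in D801N against WT, all with the opposite sign, in 2 comparisons that share the D801N libraries. Th was at 22.7 ± 18.1 CPM in E815K and 209 ± 53.7 CPM in D801N (log2 fold change -3.39 ± 0.39, edgeR's adjusted p = 0.00212), and Rtl1 (-3.84), Trbc2 (-3.47), Agmat (-2.67) and Fndc1 (-2.25) were also lower in E815K. Higher in E815K were Syt6 (1.95), Myo15a (1.95), Necab2 (1.64), a calcium-binding protein gene, Fchsd1 (1.44) and Dbp, a transcription factor under control of the circadian clock (70.6 ± 8.09 against 26.6 ± 4.53 CPM, 1.41 ± 0.26, edgeR's adjusted p = 0.0254). Mouse number and genotype are confounded here except through WT. With the range term 0 of 240 genes were called. All of them, picked in the fit without the term, kept their direction, and 203 kept an unadjusted p under 0.05 (median log2 fold change 0.61 before and 0.57 after, median SE 0.1 and 0.18). Log2 fold changes went to -2.91 for Th and 0.25 for Dbp with the term. The count was 82 without E815K_558, 93 without E815K_557, 115 without D801N_440 or E815K_556, 119 without E815K_555, 151 without D801N_439 and 369 without D801N_442.

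Cortex gave no called gene in any of the 3 comparisons. In D801N against WT the genes with the smallest p were Chrm5, a muscarinic receptor gene (2.06 ± 0.34), Nat8f3 (-1.08 ± 0.18) and Prl, which encodes the pituitary hormone prolactin and had 7 counts in D801N and 3332 in WT, where it was at 82.7 CPM in WT_550 and 0 in WT_561. Their edgeR adjusted p was 0.311. In E815K against WT they were Stac2, a regulator of calcium channels (62.9 ± 4.18 against 84.7 ± 2.60 CPM, -0.43 ± 0.066, 0.443), Olfm3 (-0.42) and A2m, a protease inhibitor (1.44). In E815K against D801N they were the potassium channel gene Kcnh4 (0.72 ± 0.094) and the ubiquitin ligase gene Traip (0.94 ± 0.13), both with edgeR's adjusted p = 0.0687, and the clock gene Per2 (0.88 ± 0.13, 0.0899). Choroid plexus genes had a median of 1.76 in E815K against WT with 0 of 16 called (15 rose adjusted over the list alone; camera adjusted p = 2.39e-13, and adjusted p = 0.358 with an estimated correlation), and oligodendrocyte genes a median of -0.24 (camera adjusted p = 1.16e-10, and adjusted p = 0.25 with an estimated correlation). Glial genes that rose in E815K brainstem were not called in cortex, but the 4 E815K cortices lay above the 4 WT cortices for Itgax (0.833 to 2.39 against 0.241 to 0.44 CPM), Clec7a (0.417 to 2.33 against 0.0249 to 0.237 CPM), C4b (24.6 to 51 against 11 to 22.9 CPM) and Gfap (143 to 258 against 84.9 to 109 CPM), with edgeR's adjusted p from 0.622 (Clec7a) to 0.933 (Gfap). edgeR called 0 genes in D801N against WT, E815K against WT and E815K against D801N, with 2042, 1160 and 2364 genes at an unadjusted p under 0.05. If no gene differed, a share of 0.05 of the 21197 genes tested would be due, and the 1160 of E815K against WT lie near it. DESeq2's Wald test called 67, 26 and 182, and limma voom 0 in each. Without a filter on low counts edgeR called 713, 406 and 795. Leaving out D801N_442 gave 5 calls between the mutants, and leaving out D801N_439 gave 1 between D801N and WT.

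Hippocampus gave no called gene either. In D801N against WT the genes with the smallest p were Plpp3, a lipid phosphatase gene (191 ± 12.4 against 241 ± 5.21 CPM, -0.34 ± 0.054), the predicted gene Gm14637 (2.27) and Bmp3, a growth factor gene (18.2 ± 3.61 against 6.49 ± 0.640 CPM, 1.49 ± 0.24), with edgeR's adjusted p = 0.261. In E815K against WT they included Rara, a retinoic acid receptor gene (0.45), and the pseudogene Mid1-ps1 (-2.28), with edgeR's adjusted p = 0.732. In E815K against D801N they were Dbp (47.3 ± 2.94 against 18.3 ± 3.80 CPM, 1.37 ± 0.20), Stxbp5l (-0.78) and the pseudogene Rpl14-ps1 (0.71), with edgeR's adjusted p = 0.227. Sodium channel genes had a median of 0.18 in D801N with 0 of 12 called (0 adjusted over the list alone; camera adjusted p = 0.000281, and adjusted p = 0.167 with an estimated correlation). Choroid plexus genes had a median of -1.28 in E815K with 0 of 16 called (11 fell adjusted over the list alone; camera adjusted p = 6.77e-19, and adjusted p = 0.295 with an estimated correlation). Their marker Ttr was at 18.6 CPM in E815K_556, 839 to 2050 CPM in the other E815K hippocampi and 1930 to 2600 CPM in WT. E815K_557 had the highest hippocampal levels of Itgax (3.35 CPM), Clec7a (2.38), C4b (122) and Gfap (779). edgeR called 0 genes in the 3 comparisons, in the order given, with 1978, 925 and 2006 genes at an unadjusted p under 0.05. If no gene differed, a share of 0.05 of the 20761 genes tested would be due, and the 925 of E815K against WT lie below it. DESeq2's Wald test called 176, 14 and 243, and limma voom 0 in each. Without a filter on low counts edgeR called 151, 60 and 198. Without D801N_439 there was 1 call in each of the 2 comparisons with D801N.

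Averaged over the 4 regions of each mouse, few genes separated the genotypes. The smallest p in D801N against WT belonged to D430019H16Rik (log2 fold change 0.68 ± 0.082, limma adjusted p = 0.0842), Peg10, an imprinted retrotransposon-derived gene (0.54 ± 0.073, 0.0978), and Srxn1, which encodes the antioxidant enzyme sulfiredoxin (0.49 ± 0.067, 0.0978). In E815K against WT they were Gm47761 (0.92 ± 0.11, 0.0732), Ctss (0.80 ± 0.10, 0.0732) and Csf1r (0.51 ± 0.070, 0.105). Between E815K and D801N limma called 6 of 18760 genes, with Igfbp5, which encodes a binding protein of insulin-like growth factors (0.78 ± 0.10), Tnxb (0.57), the stress-induced transcription factor gene Ddit3 (0.41) and the ferritin gene Ftl1 (0.28) higher in E815K, and the protocadherin gene Pcdh17 (-0.40) lower, each with adjusted p = 0.0415. limma called 0 genes in the comparisons with WT, with 1699 (D801N) and 1012 (E815K) at an unadjusted p under 0.05. edgeR on summed counts called 15 and 8, and voom on all libraries with a correlation within mice 147 and 121. Between E815K and D801N these alternatives called 35 and 629. Without single mice the highest counts were 9 (D801N, without D801N_442) and 11 (E815K, without E815K_558). The 6 calls became 0 without D801N_440 or E815K_557 or E815K_558, 2 without E815K_555, 3 without D801N_439 and 24 without D801N_442, and 0 with the range term.

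The effect of D801N differed among regions for 471 of 24069 genes and that of E815K for 42, by edgeR's quasi-likelihood test of the 3 region by genotype terms. The D801N log2 fold changes of Th were -0.41 in brainstem, 7.01 in cerebellum, -0.60 in cortex and 1.27 in hippocampus (adjusted p = 2.77e-08 for the difference). Srxn1 (0.15, 1.36, 0.22 and 0.25, in the same order), D430019H16Rik (0.31, 2.33, 0.09 and 0.04), Mtmr11 (0.08, 1.43, -0.12 and 0.09) and Trbc2 (-0.10, 7.73 and -0.19, not tested in hippocampus) also had their largest value in cerebellum. For E815K, the microglial genes Tyrobp (1.97, 2.17, 0.25 and 0.30), Csf1r (0.84, 0.83, 0.20 and 0.19), Trem2 (1.47, 1.03, 0.18 and 0) and Laptm5 (1.03, 0.98, 0.14 and 0.16) had larger values in brainstem and cerebellum than in cortex and hippocampus, and Stac2 was positive in cerebellum and hippocampus and negative elsewhere (-0.39, 0.43, -0.43 and 0.15). With the mouse as a block, which fits the pairing of the libraries, 1348 genes were called for D801N (470 of the 471 among them) and 135 for E815K (all 42 among them). The D801N count fell to 167 without WT_550, 194 without WT_561, 230 without D801N_439, 258 without D801N_440 and 307 without D801N_436. The E815K count was 8 without WT_550, 13 without WT_430, 15 without E815K_556, 23 without WT_561 or E815K_555, 25 without E815K_557 and 26 without WT_434.

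The sex by genotype term of D801N was called for 2 of 18760 genes, Gm7292 (difference of log2 fold changes, male minus female, 5.85, adjusted p = 0.000847) and Ahcyl, a relative of the S-adenosylhomocysteine hydrolase genes (6.57, 0.00108), by limma. Ahcyl was at 0 to 0.794 CPM in the females D801N_439 and D801N_440 in all regions and at 8.29 CPM or more in the other 10 mice. With 2 D801N females, a difference between sexes was not separated from one between single mice, and Gm7292 also differed between the WT males in brainstem (52.6 CPM in WT_434 and 104 CPM in WT_561). For E815K limma called 0 genes, with 312 at an unadjusted p under 0.05 and Btg2, an early response gene, at the smallest adjusted p of 0.225, and edgeR on summed counts called 2. Without D801N_436 the count was 4139, a fit in which D801N_442 is the lone D801N male and is assumed to vary like the other groups, and without WT_561 the E815K count was 3.

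In cerebellum some genes were called higher in both mutants. Of the 388 genes higher in D801N and the 26 higher in E815K, 20 were shared, against 0.482 for independent lists, a value that leaves out the shared WT libraries. In 20 simulations of unchanged groups, both comparisons shared simulated WT libraries. There edgeR called at most 1 gene per comparison, too few to give an overlap to compare with. With separate pairs of WT mice for each mutant, an alternative chosen after seeing the data, edgeR called 81 to 125 genes higher in D801N, 0 to 3 in E815K and 0 or 1 in both over 6 assignments, too few to show how much of the overlap comes from the shared WT libraries. No gene was called lower in E815K. The genes Itgax, Ccl3, Clec7a, Serpina3n, C4b, Tyrobp, Mpeg1, Gfap, Lyz2 and Hvcn1 were called in E815K brainstem and in both mutant cerebella, as were Irf8, Ctss, Hexb, Csf1r and the 3 C1q genes, 17 genes in all. In these 3 comparisons the log2 fold changes were 2.08, 1.5 and 2.23 for C4b and 1.70, 1.39 and 1.78 for Gfap. With the range term Itgax was still called in both cerebellar comparisons, and the other 9 of the first 10 genes in none of the 3. All 10, picked in the fits without the term, kept their direction, with log2 fold changes then of 1.97, 1.6 and 2.13 for C4b and 1.71, 1.27 and 1.91 for Gfap. The 2 cerebellar comparisons share the WT libraries, and the brainstem comparison comes from the same WT and E815K mice. Across genes, which are not independent replicates, log2 fold changes of the 2 mutants against WT correlated with r = 0.326 in brainstem, 0.474 in cerebellum, 0.420 in cortex and 0.447 in hippocampus. In 20 simulations of unchanged groups with shared simulated WT libraries, mean r was 0.494, 0.5, 0.492 and 0.501. The covariance was 0.0693 in cerebellum and 0.0491 in the simulations (0.0453 to 0.0552), and in the other 3 regions it lay within the simulated range. The simulations drew genes independently, while real genes vary together within a mouse. Their range is therefore too narrow to judge the cerebellar value. With separate pairs of WT mice for each mutant, r in cerebellum ran from -0.073 to 0.188 and the covariance from -0.0193 to 0.0401 over 6 assignments.

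Over all lists, camera with the preset correlation called 137 of 330 tests, 78 upward and 59 downward. With an estimated correlation 0 were called (lowest adjusted p = 0.142), and fry called 13. The lowest adjusted p of fry was 0.00854 for activated microglia, homeostatic microglia, activity-regulated secreted factors and mitochondrially encoded genes. It was 0.0134 for reactive astrocytes, 0.0251 for sodium channels, 0.0275 for calcium channels and 0.0327 for granule cells. Within the lists edgeR called 127 single gene values, of which 28 were in the list of activated microglia, 18 in that of homeostatic microglia and 16 in that of reactive astrocytes.

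Genes near Atp1a3 could differ because they stay linked to the mutant allele during breeding, so calls within 10 Mb of it (gene order of GRCm38) were counted. In E815K brainstem 4 of 339 neighbours were called, Axl, Cd22, Tyrobp and Fxyd1, against 102 of 19706 other genes (two-sided Fisher's exact p = 0.105). In D801N cerebellum 5 of 339 were called, Capns1, Bbc3, Apoe, Aplp1 and Tyrobp, against 609 of 19905 (two-sided Fisher's exact p = 0.108), and in E815K cerebellum 1 of 339, Tyrobp, against 25 of 19905 (two-sided Fisher's exact p = 0.356). Within 5 Mb, 0 of 162 genes were called in D801N cerebellum against 614 of 20082 (two-sided Fisher's exact p = 0.0173), with an unadjusted p under 0.05 for 16% of the 162 and 17.4% of the others. Within 20 Mb, 9 of 539 were called there against 605 of 19705 (two-sided Fisher's exact p = 0.0728).

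Clock genes followed the mouse numbers in direction in most cases, though not always in size. Dbp was at 42 to 82.5 CPM in the E815K mice over all regions and at 14.2 to 33 CPM in the D801N mice, while in WT it was at 22.3 to 35.5 CPM in WT_430 and WT_434 and at 43.1 to 77.4 CPM in WT_550 and WT_561. In cerebellum the WT values were 32.4 and 31.7 CPM against 67.5 and 75.6 CPM. On the log2 scale E815K exceeded D801N by 1.37 in brainstem, 1.41 in cerebellum, 1.42 in cortex and 1.39 in hippocampus. WT mice of the high range exceeded those of the low range by less, 0.77, 1.15, 1.19 and 0.79 in the same order. Of 36 cases in which a clock gene differed between the mutants at an unadjusted p under 0.05, the WT mice of the high and low ranges differed in the same direction in 34. The WT difference was a median of 0.7 of that between the mutants. These cases repeat 15 genes over regions of the same mice, so they are not independent.

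**Figure D4:**
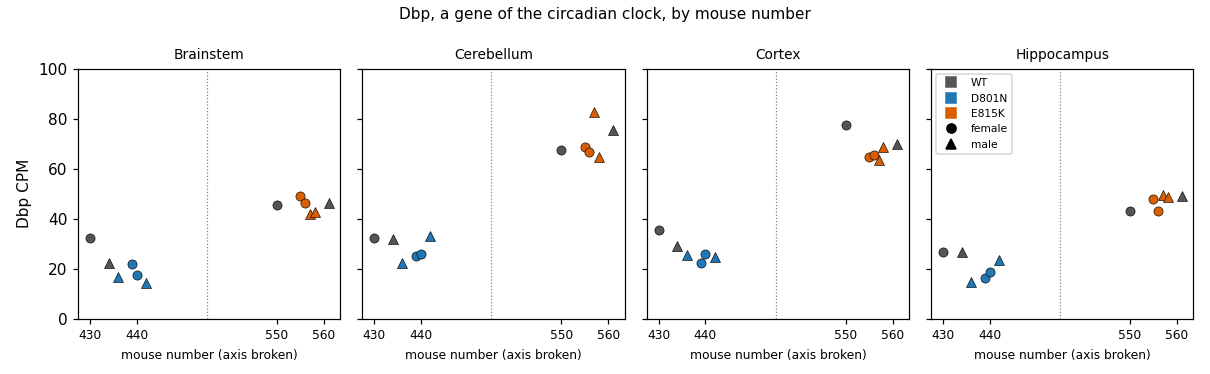
Dbp (y axis, CPM) against mouse number (x axis, broken between the ranges) in each region. Points are mice, coloured by genotype (circles female, triangles male). In each region the mice of the low range, WT_430 and WT_434 included, lie below the mice of the high range, WT_550 and WT_561 included.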

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

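The tests of explanations in this part were chosen after the results were seen. The comparisons of regions and sexes, the search for samples far from the rest and the counts over other splits of the mice were planned.

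In E815K, some microglia and reactive astrocyte genes were higher than in WT in brainstem and cerebellum, with 41 calls of list members. None of their lists held in camera with an estimated correlation (lowest adjusted p = 0.142). Over all comparisons of a mutant with WT, the lowest adjusted p of limma's fry was 0.00854 for activated and for homeostatic microglia. For reactive astrocytes it was 0.0134. Over the 41 calls the difference between WT mice of the high and low ranges was a median of 0.03 of the E815K change (quartiles -0.05 and 0.1). Genes with a wide spread among WT mice are seldom called, and 2 WT mice were set against 2. This ratio therefore does not settle whether the 2 ranges of mouse numbers contribute. Carried-over choroid plexus or meninges needs their markers to rise as much, but choroid plexus genes had a median log2 fold change of 0.13 in cerebellum (upper quartile 0.18) against 1.13 for activated microglia, and in brainstem without E815K_558 they had 0.43 (upper quartile 0.71) against 2.0, with 26 of 27 calls still made. More microglia of an unaltered kind would raise all their genes alike, but homeostatic genes had a median of 0.6 in brainstem (upper quartile 0.9) against 1.86 for activated ones (lower quartile 0.86), while in cerebellum the medians were 0.71 (upper quartile 0.93) and 1.13 (lower quartile 0.54), so that there the quartiles overlap too far to exclude it. A change of glial state in E815K, with uncalled differences of the same sign in cortex (Itgax 2.13), is a hypothesis that stays open, and an unrecorded difference between cages or litters was not tested.

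In D801N cerebellum, 621 genes were called. The range of mouse numbers gave a median of 0.03 of the change (quartiles -0.13 and 0.2). This ratio was likewise taken over called genes, whose spread among WT mice is narrow, so it does not settle whether the ranges contribute. With the range term 152 genes were called. Brainstem tissue in the dissection needs, for most called genes, brainstem RNA shares that the data lack. No share gives the change of 269 of the 621 genes, the other 352 need a median of 44.3%, and 50 brainstem genes allow a median of 0.715% (quartiles 0.119 and 1.96). Of the 50, 39 were higher in D801N (median log2 fold change 0.26), so a small carry-over that adds to genes high in brainstem is not excluded. For Th, carried-over catecholaminergic neurons would bring their other genes, but the highest of 5, Ddc, was at 3.25% of Th in D801N cerebellum against 300% in WT brainstem, and Dbh was at 0.471 CPM in D801N and 0.479 in WT. A response of cerebellar cells to the D801N allele, with Th made in cells that lack the rest of the pathway, is a hypothesis that may fit these values. Which cells hold Th was not tested.

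Clock genes differed between E815K and D801N, and here the range of mouse numbers is a candidate explanation. Over 36 cases in 15 genes the difference between WT mice of the high and low ranges was a median of 0.7 of the difference between the mutants (quartiles 0.58 and 0.91), with the same sign in 34, and 5 of the 36 had an edgeR adjusted p under 0.05. The cases share the same mice and are not independent. A shared time of day or season of collection could give this, but no label records either. With a term for the range edgeR called no clock gene named between the mutants, with Dbp in cerebellum at 0.25 (1.41 without the term, adjusted p = 0.902 with it) and Npas2 in brainstem at -0.37 (-0.90 without, 0.922 with), values that do not exclude a smaller effect of genotype.

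Other splits of the same 8 mice were counted for each comparison, 35 in all with the real one. In Brainstem the real split gave the most calls for E815K vs WT (106 calls, highest other 2) and E815K vs D801N (150, highest other 0). In Cerebellum it did so for D801N vs WT (621, highest other 3), E815K vs WT (26, highest other 3) and E815K vs D801N (240, highest other 2). The same held for the average of E815K vs D801N (6, highest other 1). It also held for dependence on region in D801N (471, highest other 3) and E815K (42, highest other 3). The lowest share that 35 splits can give is 1 of 35, and several comparisons of the same mice were tested. The splits alone therefore do not exclude chance. For E815K vs D801N the real split is also the split by range of mouse numbers. For the comparisons with 0 calls each of the 35 splits gives as many by construction, so the splits decide nothing about chance there. In these edgeR gave 1775 genes with an unadjusted p under 0.05 for D801N in brainstem, 2042, 1160 and 2364 in cortex and 1978, 925 and 2006 in hippocampus, and limma gave 1699 and 1012 for the averages, where DESeq2's Wald test called 55, then 67, 26 and 182, then 176, 14 and 243 in the single regions. The counts of E815K vs WT lie near or below the share of 0.05 due if no gene differed. For the comparisons with 0 calls, the highest other splits gave 13 (D801N in brainstem), 3, 3 and 1 (D801N, E815K and E815K vs D801N in cortex), 1, 3 and 1 (the same in hippocampus) and 18 and 3 (D801N and E815K averaged). The splits with 13 and 18 calls both set WT_430, WT_434, WT_550 and D801N_436 against the others. This split keeps most mice of each genotype on their own side and was picked as the largest of many. The brainstem libraries also enter the average, and no cause was tested. For the gene lists, 1 of 100 groupings reached the real 137 calls, but the highest other gave 136 and the median 90, so the margin is 1 call.

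A library lay far from the other 3 of its group in 15 of 162 groups tested, and about 1 in 20 is due by chance. The gap to the nearest library as a share of the group's range, taken on log2(CPM + 0.1) for genes, was 0.951 for the total count of WT_430 in hippocampus (32800000 against 34600000 to 34700000), 0.891 for the share of the 10 highest genes in WT_561 brainstem (12.4% against 8.77% to 9.17%) and 0.837 for the mitochondrial share in E815K_557 hippocampus (6.3% against 5.25% to 5.42%). For Atp1a3 it was 0.886 in D801N_439 cerebellum (1560 CPM against 1830 to 1870), 0.867 in E815K_555 cerebellum (1860 against 2170 to 2220) and 0.894 in WT_550 hippocampus (2690 against 2490 to 2520). D801N_442 cerebellum stood apart in Th (0.853, 289 CPM against 176 to 190), Rtl1 (0.892, 5.78 against 2.24 to 2.48) and Cabp2 (0.864, 0.668 against 1.84 to 2.15). C1qa gave 0.89 in WT_430 cerebellum (5.82 CPM against 7.2 to 7.39) and 0.851 in E815K_555 cerebellum (24.2 against 15.4 to 16.5), and Ly9 gave 0.839 in WT_430 brainstem (0.508 against 0.184 to 0.222). Cst7 in WT_550 brainstem, Trbc2 in WT_561 cerebellum and Ccl3 in WT_550 cerebellum gave 1, as their group's single library above 0.

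Effects that differed among regions had edgeR adjusted p of 6.96e-09 (D430019H16Rik), 1.01e-08 (Srxn1), 2.3e-08 (Trbc2), 2.77e-08 (Th) and 2.95e-08 (Mtmr11) in D801N, and 0.00384 (Stac2, Trem2 and Tyrobp) and 0.00391 (Csf1r and Laptm5) in E815K. The sex by genotype term of D801N had limma adjusted p of 0.000847 (Gm7292) and 0.00108 (Ahcyl), and with 2 females it was not separated from a difference between single mice.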

How the results depend on the processing

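The alternatives were planned except the robust fit, leaving out libraries that stand apart and the range term for gene lists, which were chosen after seeing the data. Counts by region are in the order D801N vs WT, E815K vs WT, E815K vs D801N, and the cause of a change was not tested unless given. DESeq2's Wald test called 55, 331 and 700 genes in brainstem (105 of the 106 and 149 of the 150 shared), 1345, 157 and 874 in cerebellum (598, 25 and 225 shared), 67, 26 and 182 in cortex and 176, 14 and 243 in hippocampus. Without a filter on low counts edgeR called 386, 468 and 857 in brainstem, 1263, 182 and 784 in cerebellum, 713, 406 and 795 in cortex, 151, 60 and 198 in hippocampus, 2 and 3 for the averages of D801N and E815K against WT, and 1101 (D801N) and 385 (E815K) for dependence on region. limma voom gave 71 for E815K vs D801N in brainstem and 11 for E815K vs WT in cerebellum. With the range term, edgeR called 0 for E815K vs WT and 0 for E815K vs D801N in brainstem, 152, 2 and 0 in cerebellum and 1 for D801N vs WT in hippocampus, and limma called 1 (E815K vs WT) and 0 (E815K vs D801N) averaged over regions. For E815K vs WT in brainstem all 106 genes kept their direction and an unadjusted p under 0.05, with a median log2 fold change of 1.14 before and 1.12 after and a median SE of 0.18 and 0.23. For E815K vs D801N an unadjusted p under 0.05 was kept by 135 of 150 genes in brainstem (SE 0.18 and 0.31) and 203 of 240 in cerebellum (SE 0.1 and 0.18). The error thus widened, but genes picked in the fit without the term tend to have a narrow spread among WT mice. A steady fold change in them was likely in advance and does not settle whether the ranges contribute. Fitting the 2 groups compared alone gave 11 for E815K vs D801N in brainstem, 241 (D801N vs WT) and 105 (E815K vs D801N) in cerebellum, 3 for E815K vs D801N in cortex and 4 for D801N vs WT in hippocampus. The robust fit gave 2 for E815K vs D801N in cortex, and leaving out libraries that stand apart gave 59 (E815K vs WT) and 369 (E815K vs D801N) in cerebellum and 5 (E815K vs D801N) in cortex. For averages, in the order above, no sex covariate gave 1, 1 and 16, summed counts 15, 8 and 35, and a correlation within mice 147, 121 and 629, and summed counts gave 2 for the sex dependence of E815K. The mouse as a replicate block gave 1348 (D801N) and 135 (E815K) for dependence on region, the 1 result in which regions of a mouse are compared, and DESeq2's likelihood ratio test gave 856 and 127. An estimated correlation gave 0 list calls, fry 13 and the range term 105, of which 91 were among the 137. The correlation of the 2 mutants with split WT pairs ran from -0.193 to 0.054 in brainstem, -0.073 to 0.188 in cerebellum, -0.119 to 0.154 in cortex and -0.079 to 0.076 in hippocampus, and was 0.353 in cortex with the stricter filter. Within 5 Mb of Atp1a3, 0 genes were called in D801N cerebellum (two-sided Fisher's exact p = 0.0173), with an unadjusted p under 0.05 for 16% of them and 17.4% of the others. In the other 192 cases the value stayed within 1.5 times or 1 SD, or on its side of the threshold.

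Without single mice, counts ran from 0 to 0, 0 to 93 and 0 to 212 in brainstem, 249 to 742, 4 to 23 and 82 to 369 in cerebellum, 0 to 1, 0 to 0 and 0 to 5 in cortex, 0 to 1, 0 to 0 and 0 to 1 in hippocampus and 0 to 9, 0 to 11 and 0 to 24 averaged over regions. They ran from 2 to 4139 (D801N) and 0 to 3 (E815K) for dependence on sex, 167 to 456 and 8 to 54 for dependence on region, and 120 to 142 for gene lists. Correlations of the mutants ran from 0.213 to 0.456 in brainstem, 0.401 to 0.56 in cerebellum, 0.354 to 0.531 in cortex and 0.349 to 0.552 in hippocampus. The Atp1a3 log2 fold change ran from -0.1 to 0.01 (D801N) and -0.08 to -0.03 (E815K) in brainstem, -0.17 to -0.08 and 0.09 to 0.17 in cerebellum, 0.1 to 0.15 and 0.06 to 0.15 in cortex, -0.06 to 0.07 and 0.11 to 0.2 in hippocampus and -0.05 to 0.04 and 0.05 to 0.11 averaged. Of 1757 values of called named genes over all alternatives, 1296 were still called, 461 were not and 0 changed sign, and of 458 uncalled values 66 were called. The alternatives reuse libraries that picked these genes, so a kept sign was likely in advance. The share of calls that were higher was 97.2% for E815K vs WT in brainstem and 85.5% with DESeq2's Wald test, 90.7% and 71% for E815K vs D801N in brainstem and 100% and 73.9% for E815K vs WT in cerebellum, and DESeq2's size factors moved it by less than 10 points in each comparison with calls. Depth limits genes such as Cst7 and Trbc2, whose WT libraries held 2 and 3 counts.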

Other observations

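The test of T cell genes and the choice of the mouse and gene values in this part were made after the results were seen, and the gene lists were planned. Several of the largest changes in D801N cerebellum lay outside the lists on glia and channels. Of 14 genes of p53 signalling and apoptosis 2 rose, Bbc3 and Cdkn1a (log2 fold change 2.31), an inhibitor of cell division, with 3 adjusted over the list alone (camera adjusted p = 0.0149, and adjusted p = 0.245 with an estimated correlation). Of 12 striatal genes 3 rose, Ppp1r1b and Tac1 among them, with 4 adjusted over the list alone (camera adjusted p = 0.0448, and adjusted p = 0.484 with an estimated correlation). Slc6a5 (0.51), the glycine transporter, rose among 7 glycinergic genes (3 rose and 1 fell adjusted over the list alone). Of 16 genes of inhibitory neurons, Gad2 (0.51), which makes GABA, and Tac1 rose and Calb2 (-0.61) and Kcnc1 (-0.42) fell (3 rose and 3 fell adjusted over the list alone). Glul and Gjb6 rose among 17 astrocyte genes (4 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.0142, and adjusted p = 0.455 with an estimated correlation). In E815K cerebellum genes of cholesterol synthesis had a median of -0.17 with 0 of 19 called (2 fell adjusted over the list alone; camera adjusted p = 7.55e-07, and adjusted p = 0.305 with an estimated correlation), and genes of endoplasmic reticulum stress had a median of 0.26 with 0 of 22 called (0 adjusted over the list alone; camera adjusted p = 4.22e-07, and adjusted p = 0.245 with an estimated correlation).

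Trbc2 was higher in D801N cerebellum, with 751 counts against 3 in WT. T cells in the tissue would bring their other genes, but the highest rise among 7 of them, that of Cd5, was 0.92% of the rise of Trbc2 (0.305 CPM in D801N and 0.251 in WT), and Cd3e had 11 counts against 4. Transcription of this segment in cells that are not T cells is a hypothesis that may account for it, and was not tested.

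The number of camera calls upward and downward among the 8 comparisons of a mutant with WT was as follows, and none held with an estimated correlation (lowest adjusted p = 0.142, for activated microglia). Activity-regulated secreted factors had 7 up and 0 down, glucocorticoid-induced genes 8 and 0, reactive astrocytes 6 and 0, activated microglia 4 and 0, endoplasmic reticulum stress 4 and 0, MHC class I 3 and 0, clock genes 3 and 0, heat shock 3 and 0, and p53 signalling, Na,K-ATPase subunits and glycinergic genes 1 and 0 each. Granule cells had 0 up and 6 down, endothelial cells and pericytes 0 and 5, Purkinje cells 0 and 3, excitatory neurons, red blood cells and hypothalamus with pituitary 0 and 2 each, and aminergic and cholinergic neurons and other ion transport 0 and 1 each. Cerebellum gives 2 of the 8 comparisons, so most granule cell calls lie in other regions, where Gabra6 was at most 10.1 CPM. Calls there do not speak for cerebellar granule cells. Homeostatic microglia had 3 up and 2 down, astrocytes 3 and 1, oligodendrocytes 2 and 3, their precursors 1 and 1, inhibitory neurons 1 and 2, interferon-induced genes 1 and 3, and immediate early genes 2 and 2. Sodium channels had 1 and 3, potassium and calcium channels and glutamate receptors 1 and 2 each, and GABA receptors 1 and 1. Nuclear genes of oxidative phosphorylation, mitochondrially encoded genes and cholesterol synthesis had 2 and 1 each, choroid plexus 4 and 2, meninges and striatum 2 and 2 each, ependyma 2 and 3, thalamus 1 and 1, and hindbrain Hox genes 2 and 0 of 2 comparisons. Dentate granule cells and genes that vary between strains had none.

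Single mice stood apart in Fkbp5, Prl and Gm7292. In D801N_442 the glucocorticoid-induced gene Fkbp5 was at 131, 125, 134 and 146 CPM in brainstem, cerebellum, cortex and hippocampus, against at most 50.2, 26.6, 50.3 and 97.9 CPM in the other mice. Prl was at 592 CPM in WT_430 brainstem and 164 CPM in WT_550 hippocampus, and at most 31 CPM in the libraries of the other 10 mice. Gm7292 fell into 3 levels, with the same mice at each level in every region. It was, in brainstem, at 0.541 and 0.548 CPM in D801N_440 and D801N_439, at 36.2 to 52.6 CPM in 7 mice and at 83.3 to 104 CPM in WT_561, E815K_557 and E815K_558. No test of a cause was run for these values.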
